A study of Homo sapiens with 4 samples.

How the data were processed

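RNA was extracted with TRIzol on day 2 after transfection of SiHa and MS751 cells. Per the labels' protocols, cells in 2 mL of medium with 10% serum received 5 µL of 20 µM siRNA and 5 µL of a lipid transfection reagent, and libraries were made from 1 µg of RNA with the NEBNext Ultra RNA kit. The labels give 1 library for each of siControl and siDDX24-1 in each line.

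The authors deposited 1 table per line with whole-number read counts per Ensembl gene, not normalized. Per the submitters' processing notes, fastp 0.23.2, HISAT2 2.0.4 and StringTie 1.3.4d were used with the GRCh38.p12 (hg38) genome, in roles that those notes do not state. The read counter, its treatment of strand and the annotation are not given in the sources used here. Every deposited count exceeded 1 CPM, computed on the table's total, in both libraries of its line (the lowest was 1.01), so genes silent in either library are not in the tables. Genes switched fully on or off are therefore absent from the counts of changed genes. For SiHa 69 gene identifiers, and for MS751 66, were listed more than once with identical values, and the 70 and 73 copies were dropped. All identifiers matched GENCODE release 29 on GRCh38, which supplied positions, transcript GC content and overlaps between exons. Symbols came from a separate list of gene names, with the GENCODE name where that list had none. Where identifiers shared a symbol (2 symbols in SiHa and 1 in MS751) the one with the highest mean was kept. Mitochondrially encoded genes took 8.13% and 9.61% of the SiHa counts and 12.1% and 12.2% of the MS751 counts (siControl first).

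Log2 CPM values (counts scaled to library size) were computed from the counts with edgeR 4.0.16 in R 4.3.3, with TMM factors between the libraries of a line and a prior count of 1. Genes with a mean of at least 1 CPM entered, and those with an absolute log2 fold of at least 1 were counted in each direction. With 1 library per group no test was made within a line. Intervals of a fold are exact conditional (Clopper-Pearson) intervals of the ratio of counts at 95%, and those of a level are exact Poisson intervals. They cover counting error at most. Reads copied by PCR without molecular identifiers are not independent molecules, so the intervals can be too narrow even for that error. They say nothing of the spread between cultures.

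The change common to both lines was tested with edgeR's quasi-likelihood test with the cell line as a block, at a Benjamini-Hochberg adjusted p of 0.05. The SE given with it is the absolute log2 fold divided by the square root of the test's F statistic. The labels do not say when or how often each line was transfected, so the p-values measure the spread between these lines and libraries. The planned condition for this test was counts of all genes. Genes under 1 CPM were missing, and the test was used because the unit was counts, with limma 3.58.1 on the folds as an alternative. The overlap of genes past 2-fold was set beside n1 × n2 / N for independent lists.

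Before the data were examined, 26 gene lists were fixed. They covered lymphangiogenic factors, agrin and basement membrane proteins, YAP and TAZ targets, rRNA processing, ribosomal proteins, DEAD-box helicases, p53 targets, interferon-stimulated genes, NF-kB genes, S phase, G2 and mitosis, the epithelial to mesenchymal transition, matrix proteases, TGF-beta, stress, hypoxia, cholesterol, oxidative phosphorylation, mitochondrially encoded genes, keratins, immediate early genes, histones, chemokines, and markers of endothelium, fibroblasts and leukocytes. The median fold of each list with at least 5 measured members was placed among 10000 random lists of equal size matched on mean expression in 20 bins, as a description of those libraries. Named genes were fixed by rule: DDX24, AGRN and the VEGF genes, the 10 highest and 10 lowest folds per line among genes with at least 5 CPM in a library and at least 20 counts in a library (clone names and pseudogenes left out), the 10 genes higher and 10 lower in both lines with the largest smaller fold, and up to 4 members per list and line past 2-fold. Members called in the list-alone adjustment, and genes of a few lists given with their counts in both lines, were named after their values were seen. A few genes that the rule takes are not reported here.

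Alternatives were other prior counts, a mean of at least 5 CPM, no filter, other scalings, symbols summed, DESeq2 1.42.0, limma settings and other random lists. Further ones, added after the data were seen, were library totals, DESeq2 size factors, removal of a smooth trend on GC content (mgcv 1.9.3), limma on the folds at a prior count of 1, random lists matched on GC content and the percentile of AGRN among genes nearest in GC content. The functions were tested on simulated counts for the 11112 shared genes with 200 changed genes. In the test common to both lines, 44.0% of genes changed 2-fold and 100% of those changed 4-fold, 8-fold or 16-fold were recovered, with 7 false calls. Each changed gene had the same fold in both lines, and every gene had the same simulated spread. The recovery therefore does not cover genes whose folds differ between the lines or whose spread is larger. Of 200 random lists in simulated SiHa libraries, 5.00% fell outside the central 95%, and all 50 lists shifted by 0.5 were found. The random lists were drawn from the same independent simulated genes as their reference lists, so their share checks the code alone. In the same simulated SiHa libraries, where every gene had the common spread of the real fit, 302 of 10912 unchanged genes passed 2-fold.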

Results

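The data were RNA-seq gene counts from SiHa and MS751, both established squamous cell carcinoma lines of the human cervix. Each line was transfected either with a control siRNA (siControl) or with siDDX24-1, a small interfering RNA directed at the transcript of DDX24, and RNA was taken on day 2. There were 4 libraries and 4 groups, so each group held 1 library. The counts of the listed genes summed to 17707551 in SiHa siControl, 20117442 in SiHa siDDX24-1, 13160487 in MS751 siControl and 14664797 in MS751 siDDX24-1. There were 12191 genes listed for SiHa and 12037 for MS751, all protein-coding, and no gene had fewer than 14 counts in a library. Because no group had a replicate, differences within a line have no replicate check and carry no p-value. The 95% intervals given with them cover counting error at most, and folds are siDDX24-1 over siControl on a log2 scale.

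DDX24, a DEAD-box RNA helicase, was lower in both libraries labelled siDDX24-1. The gene (ENSG00000089737) lies on chromosome 14 from 94048291 to 94081245 on the minus strand of GRCh38. In SiHa it had 3464 counts (192 CPM) with siControl and 575 counts (29.2 CPM) with siDDX24-1, which is 6.55-fold lower (log2 fold -2.71, 95% interval -2.84 to -2.59). In MS751 it had 2072 counts (157 CPM) with siControl and 993 counts (68.0 CPM) with siDDX24-1, which is 2.30-fold lower (log2 fold -1.20, 95% interval -1.31 to -1.09). Exons of DDX24 overlap those of OTUB2, and the way the authors' counting treated shared positions is not given in the sources used here.

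**Figure D1:**
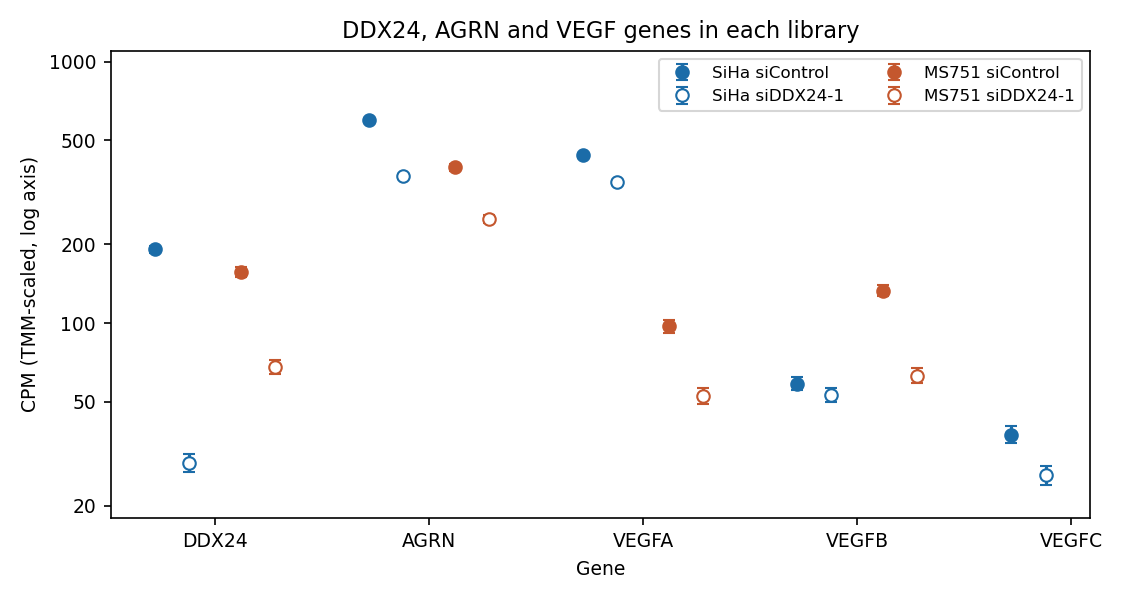
Level of 5 genes in each library, in CPM after TMM scaling, on a log axis. Filled points are siControl and open points siDDX24-1, blue is SiHa and orange MS751, and bars are 95% Poisson intervals of the single library. DDX24 went from 192 to 29.2 CPM in SiHa and from 157 to 68.0 CPM in MS751, and VEGFC is plotted for SiHa alone because the MS751 table did not list it.

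The title of the series links DDX24 to lymphangiogenesis through AGRN, which encodes agrin, a heparan sulphate proteoglycan of basement membranes. AGRN (ENSG00000188157, chromosome 1, 1020123 to 1056118, plus strand of GRCh38) had 10838 counts with siControl and 7167 with siDDX24-1 in SiHa, a log2 fold of -0.72 (95% interval -0.76 to -0.68). In MS751 it had 5203 and 3648 counts, a log2 fold of -0.66 (95% interval -0.72 to -0.59). The study chose AGRN, possibly on these libraries, so these values are not independent evidence of its direction. AGRN transcripts are rich in GC (67.5%), and GC-rich genes were lower as a class in both knockdown libraries. Among the 400 genes nearest to it in GC content, a comparison added after the AGRN values were seen, its fold lay at percentile 21.6 in SiHa and 53.7 in MS751. With a smooth trend on GC content removed, the AGRN fold was -0.35 in SiHa and 0.055 in MS751.

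Of the secreted growth factors of blood and lymphatic vessels, VEGFA had log2 folds of -0.34 in SiHa (95% interval -0.39 to -0.30) and -0.89 in MS751 (95% interval -1.02 to -0.76). Removing the GC trend left VEGFA at -0.30 and -0.86. VEGFB had log2 folds of -0.15 and -1.08, and with the GC trend removed these were 0.20 and -0.41. VEGFC, the main lymphatic growth factor, was listed in SiHa alone, with 678 counts with siControl and 515 with siDDX24-1 (log2 fold -0.52, 95% interval -0.69 to -0.35). VEGFD was listed in neither table. The list of lymphangiogenic and angiogenic factors had 18 members measured in each line, among them SEMA3F, an inhibitor of vessel growth. SiHa had 1 member past 2-fold, SEMA3F (log2 fold -1.18). The list median in SiHa was -0.07 (mean -0.13), at percentile 17.4 of 10000 expression-matched random lists. MS751 had 3 past 2-fold, all lower (IGF2 at -1.57, ADM at -1.09 and VEGFB), and a list median of -0.40 at percentile 1.28. That percentile became 12.5 when the random lists were also matched on GC content.

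Agrin's partners and other basement membrane genes had folds in both directions. In SiHa, DAG1, which encodes the agrin and laminin receptor dystroglycan, went from 152 to 4734 counts (log2 fold 4.83, 95% interval 4.61 to 5.08), the highest fold among the genes named in that line. In MS751 DAG1 had 3863 and 4619 counts (log2 fold 0.11). LRP4, another agrin receptor, had 69 and 26 counts in SiHa (log2 fold -1.49). Of 25 members of the list in SiHa 1 was past 2-fold higher and 1 lower, with a median of -0.15 at percentile 2.34. That percentile became 12.4 with matching on GC content and 52.5 when the mean replaced the median. The mean was -0.03 and includes DAG1 at 4.83, while 16 of the 25 folds lay below 0. Of 19 members in MS751, 3 were past 2-fold lower (COL7A1 at -2.20, NID2 at -1.85 and HSPG2 at -1.02), with a median of -0.30 at percentile 6.72, which turned to 0.068 among genes with a mean of at least 5 CPM. Of the chemokine genes of lymph node homing, 3 were listed in SiHa and 2 in MS751, and CCR10 had log2 folds of -1.34 and -0.61.

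In SiHa, interferon-stimulated genes were lower in the siDDX24-1 library. All 40 measured members had folds below 0, 18 of them past 2-fold, and each of the 40 counting intervals lay below 0. The list median was -0.90, below that of each of the 10000 random lists (percentile 0). IFITM1, which restricts virus entry, had 1353 counts with siControl and 99 with siDDX24-1 (log2 fold -3.88), RSAD2 had a log2 fold of -2.42, SAMD9L -2.35 and IFI44 -1.61. Exons of IFITM1 overlap IFITM2 and those of RSAD2 overlap CMPK2, so their counts are less certain. NF-kB and inflammatory cytokine genes had a median of -0.54 (percentile 0), with 5 of 24 past 2-fold lower, among them IL11 (-1.67), CXCL8 (-1.65), CSF3 (-1.32) and IL1B (-1.14).

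Several other groups were lower in SiHa by smaller amounts. Immediate early genes, the first transcripts after growth factor stimulation, had a median of -0.34 (percentile 0) over 31 members, with MYC at -3.40 (942 to 96 counts) and IER2 at -2.14 past 2-fold. The p53 targets had a median of -0.29 (percentile 0.02) over 27 members, with GDF15 at -1.86. Hypoxia and glycolysis genes had a median of -0.23 (percentile 0) and none of 34 past 2-fold. Matrix proteases and their inhibitors had a median of -0.17 (percentile 0.2), and this percentile was 3.09 against unmatched random lists. Squamous keratins and differentiation genes had a median of -0.19 (percentile 0.76), with 4 of 18 past 2-fold lower, PKP1 (-2.30), S100A9 (-1.34), KRT16 (-1.32) and KRT15 (-1.09). That percentile became 12.5 with matching on GC content and 3.80 against unmatched random lists, and the list mean was -0.43 at percentile 0.

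Genes of cell division and of ribosome assembly were slightly higher in the SiHa knockdown library. Of 27 replication-dependent histone genes 26 had folds above 0, with a median of 0.57 (percentile 100), and 4 were past 2-fold higher, H2AC13 (1.33), H4C8 (1.24), H3C10 (1.20) and H2BC11 (1.00). Genes of G2 and mitosis had a median of 0.29 (percentile 100) with 41 of 43 above 0, but AURKA, a mitotic kinase, was at 1.33 and FOXM1, a transcription factor of the same phase, at -1.53. Genes of S phase and DNA replication had a median of 0.18 (percentile 99.7), with 1 member past 2-fold higher and 1 lower, the latter GINS4 at -1.24. Factors of rRNA processing and ribosome assembly had a median of 0.16 (percentile 99.7), with NOLC1 at 1.09, and cytosolic ribosomal proteins a median of 0.15 (percentile 98.6). The 13 mitochondrially encoded genes had a median of 0.33 (percentile 99.7), and their share of the counts was 8.13% with siControl and 9.61% with siDDX24-1.

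Across the 12189 genes compared in SiHa, 178 were at least 2-fold higher and 372 at least 2-fold lower with siDDX24-1, and 19 and 34 of these passed 4-fold. In simulated SiHa libraries with the common spread of the real fit, 302 of 10912 unchanged genes passed 2-fold. An unknown part of the observed counts may therefore be spread alone. After DAG1, the highest folds among genes eligible for naming belonged to CBL (3.80), which encodes a ubiquitin ligase, MDM4 (2.88), an inhibitor of p53, FMC1-LUC7L2 (2.88), KLHL26 (2.78), MSRB3 (2.49), RNF182 (2.49), CYB561D1 (2.47) and PLEKHA2 (2.36). The lowest were RAB43 (-3.97), a small GTPase, IFITM1, EDN2 (-3.54), which encodes endothelin 2, MYC, LRRC8E (-3.28), MINDY2 (-2.91), ZNF24 (-2.86), DNAJC27 (-2.75), BMF (-2.75) and DDX24 itself. Exons of CBL overlap MCAM, FMC1-LUC7L2 is annotated over FMC1 and LUC7L2, and RAB43 overlaps ISY1-RAB43, so the counts of these genes are uncertain. The fold was related to transcript GC content across genes (Spearman's rho -0.34, with genes not independent replicates), and genes at least 2-fold lower made up 67.6% of those past 2-fold, or 56.0% with the GC trend removed.

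In MS751, genes of DNA replication and ribosome assembly were higher in the siDDX24-1 library. Genes of S phase and DNA replication had a median of 0.79 (percentile 100), with 40 of 43 above 0 and 14 past 2-fold higher, among them MCM10 (1.83), CLSPN (1.81), CCNE2 (1.80) and RRM2 (1.79). Factors of rRNA processing and ribosome assembly had a median of 0.67 (percentile 100), with 13 of 52 past 2-fold higher, including NOLC1 (1.96), POLR1A (1.94), which encodes the largest subunit of RNA polymerase I, UTP20 (1.84) and DDX21 (1.64). Other DEAD-box RNA helicases had a median of 0.40 (percentile 99.9), 5 of 32 past 2-fold higher and 1 lower, with DDX19A at 1.60, DDX3X at 1.18 and DDX46 at 1.10 beside DDX21. Genes of G2 and mitosis had a median of 0.38 (percentile 99.9), with AURKA at 1.31 the 1 member past 2-fold.

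Immediate early genes were lower in the MS751 knockdown library, with 14 of 28 past 2-fold lower and a median of -0.96 (percentile 0). NR4A1, an orphan nuclear receptor, went from 7657 to 394 counts (log2 fold -4.42), FOSB was at -3.38 and ZFP36, which destabilises cytokine transcripts, at -2.82. IER2 went the other way, from 338 to 2006 counts (log2 fold 2.42). Genes of the amino-acid and unfolded-protein stress responses had a median of -0.44 (percentile 0), with 11 of 33 past 2-fold lower, among them DDIT3 (-2.35), PPP1R15A (-1.96), HERPUD1 (-1.82) and DNAJB9 (-1.65). Cholesterol synthesis and uptake genes had a median of -0.55 (percentile 0), with 6 of 28 past 2-fold lower, among them the sterol sensor INSIG1 (-2.52), SCD (-1.61), IDI1 (-1.59) and MVD (-1.49), and 1 higher. Hypoxia and glycolysis genes had a median of -0.37 (percentile 0), with 7 of 35 past 2-fold lower, among them CA9 (-1.74), NDRG1 (-1.50), LOX (-1.46) and ANKRD37 (-1.32).

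Smaller shifts in MS751 included the list of matrix proteases and their inhibitors, with a median of -0.33 (percentile 0.68). Its members past 2-fold were ADAM8 (180 to 49 counts), PLAT (-1.14) and LOX, which encodes a collagen crosslinking enzyme and not a protease. Cytosolic ribosomal proteins had a median of -0.19 (percentile 0), nuclear genes of oxidative phosphorylation -0.09 (percentile 1.47) and TGF-beta targets and pathway genes -0.29 (percentile 2.42), each with no member past 2-fold. The percentiles of oxidative phosphorylation and TGF-beta genes became 7.41 and 9.16 when the mean replaced the median. Interferon-stimulated genes had a median of -0.23 (percentile 4.24, or 0.98 with matching on GC content and 1.25 among genes with a mean of at least 5 CPM), with 18 of 36 counting intervals below 0 and 9 above 0. Of these genes 5 were past 2-fold lower, among them IFITM1 (-1.73), OASL (-1.57) and IFI6 (-1.12), and HERC6 was past it in the other direction (1.45).

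Across the 12036 genes compared in MS751, 450 were at least 2-fold higher and 1029 at least 2-fold lower, and 39 and 150 of these passed 4-fold. The highest folds belonged to ZBTB38 (4.22), KTI12 (3.29), CRAMP1 (3.03), TUB (2.86), RC3H1 (2.64), HOXC6 (2.64), RASAL2 (2.61), TFEC (2.56), MED29 (2.53) and PSME3 (2.52), a proteasome activator. The lowest belonged to the nuclear receptors NR4A2 (-4.50), NR4A1 and NR4A3 (-4.00), GIPR (-4.18), CAPN12 (-3.83), FOSB, RAB43 (-3.31), ESPN (-3.30), the serine protease gene PRSS8 (-3.22) and RNF125 (-3.20). Exons of KTI12, CRAMP1, TUB, HOXC6, RASAL2, PSME3, CAPN12 and ESPN overlap those of other protein-coding genes. The relation of the fold to transcript GC content had a Spearman's rho of -0.37 across genes, and the genes at least 2-fold lower had a median GC content of 58.1% against 44.0% for those at least 2-fold higher.

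**Figure D2:**
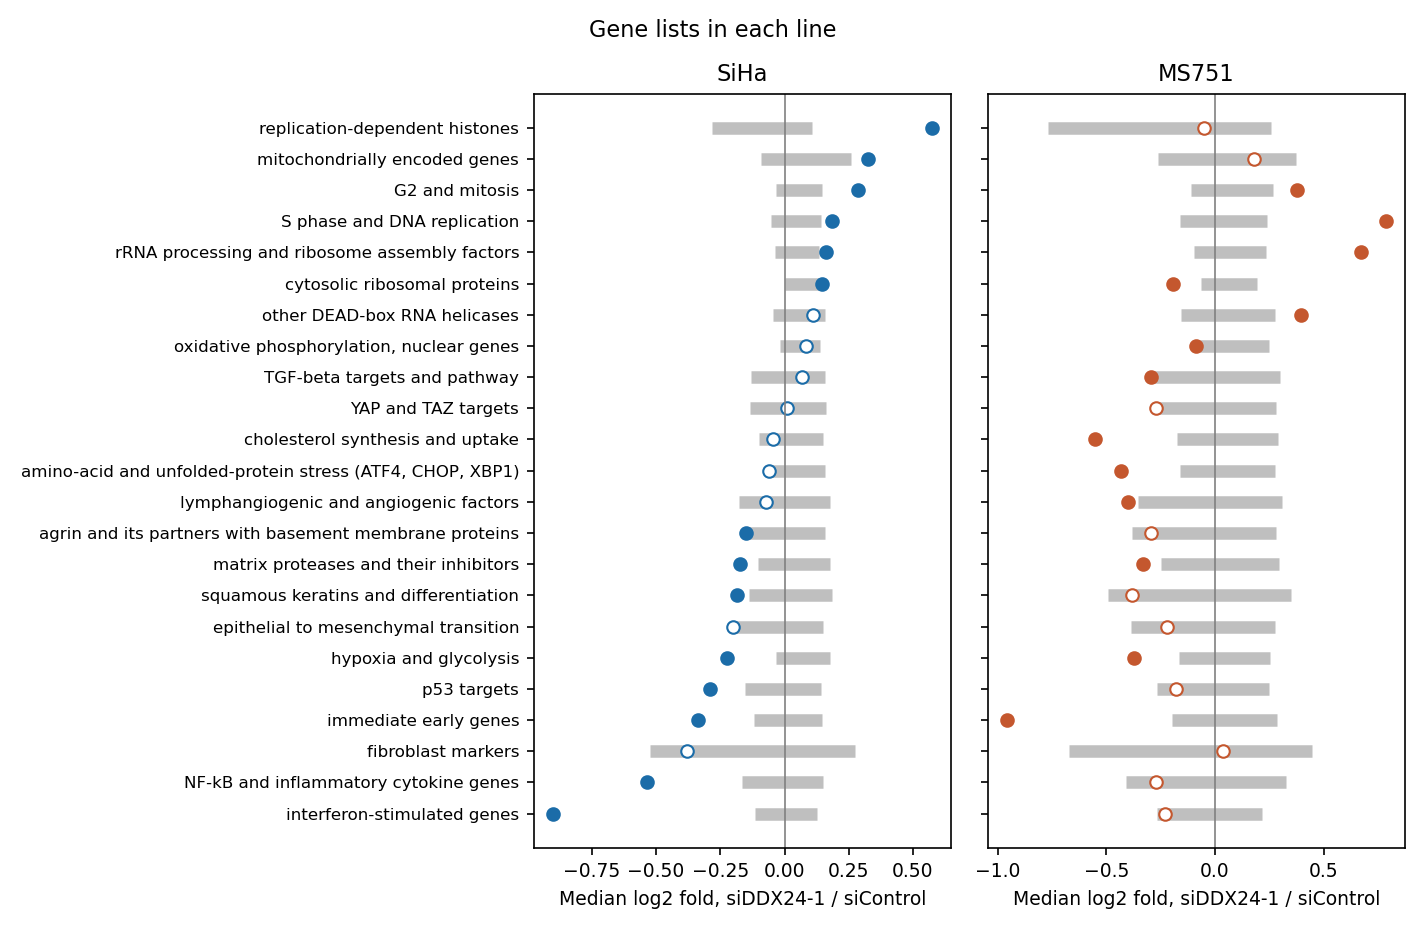
Median log2 fold (siDDX24-1 over siControl) of each gene list with at least 5 measured members, SiHa at left and MS751 at right, each with its own horizontal scale. Grey bars span the central 95% of 10000 random lists matched on mean expression, and filled points lie outside that span. Interferon-stimulated genes have the lowest median in SiHa (-0.90), and immediate early genes the lowest in MS751 (-0.96).

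**Figure D3:**
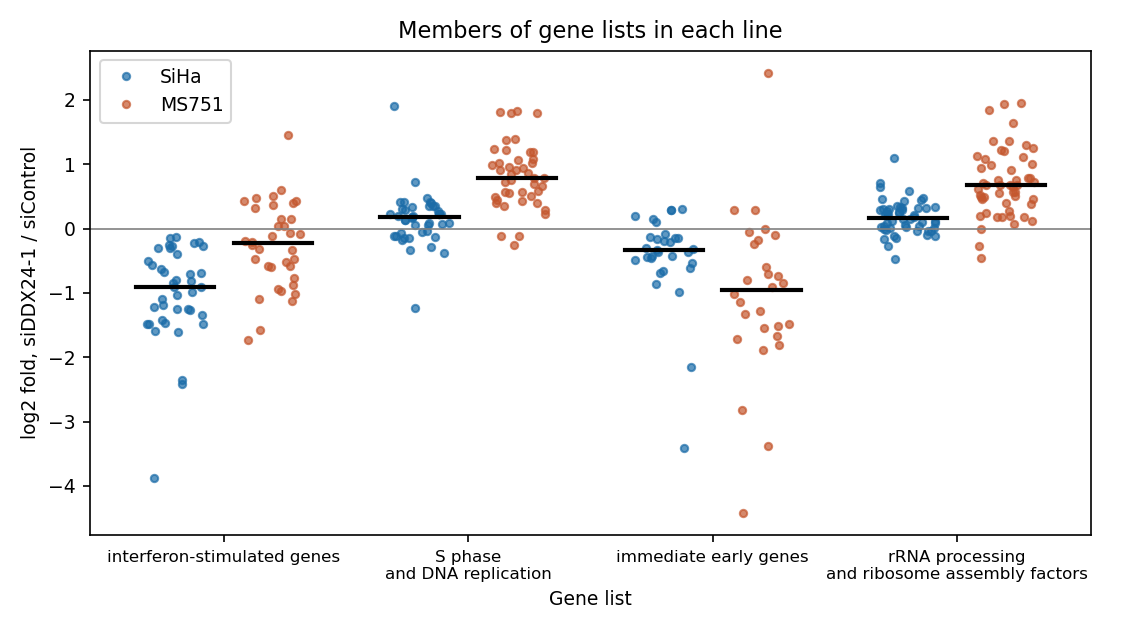
Log2 fold (siDDX24-1 over siControl) of each measured member of 4 gene lists, with SiHa in blue and MS751 in orange, and black lines at the medians. All 40 interferon-stimulated genes lie below 0 in SiHa, while 13 of 36 lie above 0 in MS751.

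The remaining lists with at least 5 measured members had medians within the central 95% of their random lists. In SiHa these were YAP and TAZ targets (median 0.01), other DEAD-box helicases (0.11), TGF-beta targets and pathway genes (0.07), amino-acid and unfolded-protein stress genes (-0.06), cholesterol genes (-0.04, mean -0.018), nuclear oxidative phosphorylation genes (0.08) and genes of the epithelial to mesenchymal transition (-0.20). The last of these was at percentile 2.77, or 1.08 with matching on GC content. It had 1 member past 2-fold higher, SNAI2 at 1.25, and 1 lower. The TGF-beta list had 1 member past 2-fold higher and 2 lower, among them the receptor gene TGFBR1 (-2.21). In SiHa the YAP and TAZ, DEAD-box, stress, cholesterol and oxidative phosphorylation lists had none past 2-fold. The means of the YAP and TGF-beta lists in SiHa were -0.02 and -0.09, opposite in sign to their medians. In MS751 these lists were YAP and TAZ targets (median -0.27), p53 targets (-0.18), NF-kB genes (-0.27), the epithelial to mesenchymal transition (-0.22), mitochondrially encoded genes (0.18), squamous keratins (-0.38) and replication-dependent histones (-0.05). Past 2-fold in MS751 were 2 YAP and TAZ targets, both lower, such as GADD45B (-1.98), 4 p53 targets, all lower, such as BBC3 (-1.98), and 3 keratin and differentiation genes, all lower, such as SFN (-2.18). The transition list had 2 higher, such as OCLN (1.93), and 4 lower, and the NF-kB list 1 each way. Because the transition list holds epithelial genes such as OCLN beside drivers such as SNAI2, its medians give no direction of the transition. The YAP and TAZ list was at percentile 2.89, or 2.49 among genes with a mean of at least 5 CPM. Among those genes the MS751 medians of the transition and histone lists were -0.12 and -0.08.

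Markers of other cell types were mostly unlisted. Of 15 leukocyte markers 3 were listed in SiHa and 1 in MS751, with none past 2-fold, and of 18 endothelial markers 3 were listed in each line, with STAB1 in MS751 at 115 and 15 counts. Of 13 fibroblast markers 6 were listed in SiHa (median -0.38) and 7 in MS751 (median 0.04, mean -0.26, and median -0.33 at a mean of at least 5 CPM), with COL1A1 at -1.16 and -1.86.

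Genes past 2-fold in both lines shared a direction more often than independent lists would. Among the 11112 genes in both tables, 27 were at least 2-fold higher in both lines, against 5.61 for independent lists of those sizes, and 100 were at least 2-fold lower in both, against 22.5. Opposite directions were seen for 12 genes higher in SiHa and lower in MS751 (10.9 for independent lists) and for 15 genes of the other kind (11.6). Each line had its own control library, so the folds share no library. Across genes, which are not independent replicates, the folds of the lines had a Pearson correlation of 0.33 and a Spearman correlation of 0.38. With the GC trend removed from each line the Pearson correlation was 0.24, and 47 genes were lower in both lines, against 11.6 for independent lists.

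The genes higher in both lines with the largest smaller fold were FMC1-LUC7L2 (2.88 in SiHa and 2.31 in MS751), RAB31 (2.12 and 2.16), MDM4 (2.88 and 1.79), MC1R (1.61 and 1.72), KAT6A (1.57 and 2.42), ARMT1 (1.41 and 2.46), MAPK14 (1.45 and 1.40), KCTD20 (1.39 and 1.99), MESD (1.53 and 1.37) and STOX1 (1.77 and 1.36). Those lower in both lines were RAB43 (-3.97 and -3.31), BMF (-2.75 and -2.44), a BCL2 family member that promotes cell death, AFF1 (-2.26 and -2.45), BLOC1S6 (-2.15 and -2.10), MIEF2 (-2.04 and -2.68), IFITM1 (-3.88 and -1.73), CRABP2 (-1.97 and -1.70), PLA2G15 (-2.03 and -1.70), HES7 (-1.76 and -1.98) and MAPT (-1.64 and -2.02). Exons of FMC1-LUC7L2, MC1R, KCTD20, MESD, RAB43, BLOC1S6 and IFITM1 overlap those of other protein-coding genes. Over all named genes, 37 of 136 have such an overlap, which makes their counts less certain. Among the list members these include IGF2, NID2, HSPG2, CCR10, FOXM1, CCNE2, RRM2, DDX19A, DDX46, DDIT3, DNAJB9, CA9, LOX, ANKRD37 and STAB1.

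**Figure D4:**
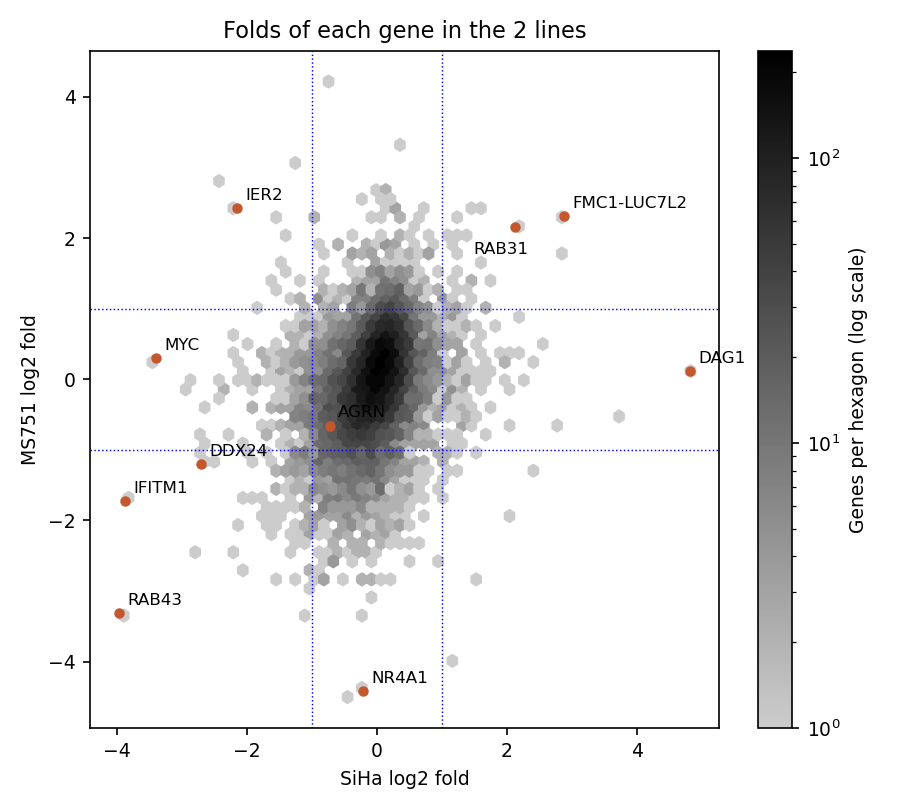
Log2 fold (siDDX24-1 over siControl) in SiHa on the horizontal axis and in MS751 on the vertical axis for the 11112 genes in both tables, with shading by the number of genes per hexagon on a log scale. Dotted lines mark 2-fold, and orange points are named genes. RAB43 lies at -3.97 and -3.31, DAG1 at 4.83 and 0.11, and IER2 at -2.14 and 2.42.

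A test of the change common to both lines, with the cell line as a block and the lines as the 2 replicates, called 5 genes at an adjusted p under 0.05 (edgeR quasi-likelihood test, two-sided, Benjamini-Hochberg adjustment over 11112 genes, 1 residual degree of freedom). FMC1-LUC7L2 rose by a log2 fold of 2.59 (SE 0.264, adjusted p = 0.0458) and RAB31, a small GTPase of vesicle transport, by 2.13 (SE 0.221, adjusted p = 0.0458). RAB43 fell by 3.66 (SE 0.309, adjusted p = 0.0416), AFF1, a scaffold of the super elongation complex, by 2.37 (SE 0.244, adjusted p = 0.0458) and BLOC1S6 by 2.15 (SE 0.232, adjusted p = 0.0488), each in both lines. DDX24 had a log2 fold of -1.97 (SE 0.358) and an adjusted p of 0.171, and AGRN a log2 fold of -0.71 (SE 0.207) and an adjusted p of 0.309, so neither passed this test. DESeq2 gave DDX24 an adjusted p of 3.08e-05 and AGRN one of 0.222, and the other settings gave DDX24 adjusted p-values from 0.0555 to 0.352. All 5 calls were lost with DESeq2 size factors in place of TMM factors and with the GC trend entered as an offset, whereas DESeq2 itself called 26 higher and 71 lower. An unadjusted p under 0.05 was seen for 1404 genes, against 555.6 by chance.

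No member of the 26 lists passed that edgeR test over all genes. Adjusted over the list alone, with no adjustment across the 26 lists, 23 members of 9 lists passed it. None of the members of the other 17 lists did. These list-alone calls were not repeated under the other settings. Of 35 interferon-stimulated genes in both tables, 9 were lower (IFI6, IFIT1, IFITM1, IRF9, ISG15, ISG20, OAS1, OAS2 and OASL), OASL by a log2 fold of -1.61 (SE 0.269). Of 28 immediate early genes, 4 were lower, ZFP36 (-1.85), EGR3 (-1.18), DUSP6 (-0.97) and JUN (-0.76). Of 15 agrin partners and basement membrane genes, 3 were lower, COL7A1 (-1.26), COL18A1 (-0.85) and AGRN, a list centred on the gene the study chose. The lowest list-adjusted p of that list was 0.0499, so these 3 passed only at the threshold. With the GC trend as an offset the AGRN log2 fold was -0.18. The others were the collagen genes COL1A1 and COL5A1 of the fibroblast list, ANGPTL4, GDF15 and CCR10, all lower, and NOLC1 (1.51) and AURKA, both higher. The fibroblast list was adjusted over 4 members and the chemokine list of CCR10 over 2.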

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

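Of the tests in this part, those on GC content, on a control culture with a higher interferon response, on seed matches and on lost reads were chosen after the results were seen. The tests on counting error and on overlapping exons were chosen before.

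Some results went opposite ways in the lines, and these differences were not tested, since each group had 1 library. Differences are MS751 minus SiHa on the log2 scale. TUB was at -2.45 in SiHa and 2.86 in MS751 (difference 5.31), CRAMP1 at -1.31 and 3.03 (4.34), IER2 at -2.14 and 2.42 (4.57), PLEKHA2 at 2.36 and -1.27 (-3.63) and NR4A3 at 1.10 and -4.00 (-5.09). The median of the cytosolic ribosomal proteins was 0.15 in SiHa and -0.19 in MS751 (-0.34).

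Interferon-stimulated genes were lower in the SiHa library treated with siDDX24-1. The values argue against a trend on GC content, since the list median stayed at percentile 0 of random lists matched on expression and GC content. They also argue against counting error, since the intervals of 40 of 40 members lay below 0. Reads copied by PCR can make those intervals too narrow. It stays open whether the siControl culture happened to have the higher interferon response to transfection. The list lay at percentile 4.24 in MS751, between the bounds set for either answer (0.98 with matching on GC content), and with 1 culture per group a culture's own state cannot be told apart from the knockdown. No biological explanation was tested for this pattern.

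Genes past 2-fold the same way in both lines outnumbered those of independent lists. A trend on GC content accounts for part of this, but the correlation across genes after its removal was 0.243 (bootstrap interval 0.220 to 0.269). The smooth trend that was removed is therefore not the whole source, though a GC effect that it missed stays possible. The bootstrap drew genes, which are not independent replicates, so its interval does not cover the spread between cultures. For seed matches the sequence of the siRNA was not used, and 15836 heptamers were scanned. Each was in the 3' UTRs of at least 100 of 10990 genes. None stood out, since the lowest sum over both lines of z, the scaled shift in fold of a heptamer's carriers, was undercut in 39 of 100 shuffles of genes. The heptamer with that sum, TTGATTA, was in 0 of 6 DDX24 transcripts. Among the 93 genes lower in both lines with a 3' UTR, the most enriched heptamer for their 3' UTR length was CGGGGCA. In 0 of 100 random sets matched on 3' UTR length was any heptamer as enriched. Matching also on GC content was added after that result because this heptamer was rich in GC. A different heptamer, CGTTCTT, was then the most enriched, and 77 of 100 random sets held a heptamer as enriched. The value of CGGGGCA itself under that matching was not computed. Over all genes tested, CGGGGCA had z values of -1.2 in SiHa and -0.63 in MS751. These z values had 3' UTR length, GC content and expression regressed out. Every shuffle of genes held a heptamer with a lower sum of z (-5.09 or below), so the carriers of CGGGGCA as a class did not stand out. The z values do not cover the 93 genes alone, so seed matches cannot be told apart from the knockdown. With 1 siRNA for DDX24, other off-target effects and any batch shared by the knockdown libraries stay open beside the loss of DDX24.

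Some genes were past 4-fold in 1 line and under a log2 fold of 0.5 in the other, 94 in all, such as DAG1 and MYC in SiHa. Reads shared with overlapping genes do not stand out, since 32 of the 94 overlap another protein-coding gene, at percentile 50 of random genes matched on expression, although individual genes with overlaps remain uncertain. Reads lost from 1 library would make the departing library the low one, which held for 60.6% of these genes (exact 95% binomial interval 50.02% to 70.56%) against 59.6% of genes 2-fold to 4-fold apart. The intervals overlap, so lost reads cannot be told apart from a change in expression here. The siControl library was the one farther from the other line's level for 48 of the 94 genes, and a response of 1 line to the knockdown, the biological alternative, was not tested.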

How the results depend on the processing

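GC removal, library totals, DESeq2 size factors, GC-matched lists and limma at a prior count of 1 were added after the data were seen. DDX24 stayed within its counting interval under every setting tried. The SiHa counts past 2-fold ranged over 146 to 209 higher and 257 to 444 lower, the MS751 counts over 399 to 460 and 749 to 1125, and genes higher in both lines over 24 to 27. Genes lower in both numbered 100 and ranged over 47 to 118, the highest with library totals, with 66 among genes with a mean of at least 5 CPM (fewer genes tested) and 47 with the GC trend removed. AGRN in SiHa was -0.78 with library totals and -0.35 with the GC trend removed. With that trend removed AGRN in MS751 turned to 0.055 and VEGFB in SiHa to 0.20. The share of lower genes past 2-fold in MS751 went from 69.6% to 62.2%.

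The common test called 2 higher and 3 lower. It called 0 and 0 both with DESeq2 size factors in edgeR (1276 genes at an unadjusted p under 0.05) and with the GC trend removed (1037). DESeq2 called 26 and 71, and limma on the folds 6 and 11, 6 and 10 with a prior count of 0.1, 6 and 10 with 5, and 0 and 1 without a trend on expression. The cause was not tested for these changes. The 5 calls were kept by DESeq2 and by limma, except that limma without a trend kept 1, RAB43. DESeq2 left 216 adjusted p-values NA. The DDX24 adjusted p was 3.08e-05 with DESeq2 and 0.0555 to 0.352 otherwise, and the AGRN adjusted p over all settings from 0.219 to 0.776.

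Over the other named genes and settings, 1087 folds stayed within their counting interval, 39 moved, 35 of these with the GC trend removed, and VEGFB reversed. List calls lost and gained numbered 3 and 2 with GC matching, 5 and 1 with unmatched lists, 3 and 0 with means, and 0 and 3 at 5 CPM. Dropping the filter removed no gene from the comparison, since the tables were already filtered, and summing symbols left each count of genes past 2-fold as it was. The planned trimmed mean of log ratios is the TMM scaling reported. Leaving out a line gives the within-line values. The common test pairs the libraries by cell line, and the labels give no replicate numbers for a further pairing. Depth limits low genes most, and genes under 1 CPM were not analysed here.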

Other observations

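The 27 genes past 2-fold in opposite directions included several that the text has not described, chosen after their values were seen. STX6, a membrane fusion protein of the trans-Golgi, had log2 folds of 2.06 in SiHa and -1.95 in MS751. ZNF10 had 1.52 and -2.83, CBLL1 -1.33 and 2.05, and GCH1, the first enzyme of tetrahydrobiopterin synthesis, -1.50 and 2.35. The immune checkpoint gene CD276 had 1670 and 510 counts in SiHa (log2 fold -1.83) and 881 and 1986 in MS751 (1.03). YWHAB, an abundant 14-3-3 protein gene, had 9015 and 4168 counts in SiHa (-1.24) and 2258 and 5451 in MS751 (1.13). These differences were not tested.

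The siControl libraries of the lines had different counts of IER2, an immediate early gene, and of NR4A3, a nuclear receptor gene outside the list of immediate early genes. IER2 had 11635 counts in SiHa siControl and 338 in MS751 siControl, and NR4A3 had 70 and 2473. The folds of both genes were opposite in the lines.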
